A study of Mus musculus with 26 samples.

How the data were processed

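The series holds 26 samples of mouse 3T3-L1 cells, a fibroblast line that differentiates into fat cells in culture. Mature adipocytes were left untreated or given 1 µM rosiglitazone, an antidiabetic agonist of the nuclear receptor PPARγ, in DMSO. The 10 GRO-seq samples, which measure nascent RNA, and the input sample were not analysed here. The 15 ChIP-seq libraries analysed here each came with a peak list. MED1 had 2 untreated and 2 rosiglitazone lists, numbered by replicate in the labels. CBP, p300 and NCOR had 1 list per condition. CEBPa, CEBPb, ATF2, JUND and FOSL2 had 1 untreated list each. The labels give no treatment time for ChIP-seq. The peak names inside the second MED1 rosiglitazone list carry the word 1h and those inside the NCOR rosiglitazone list carry 30m, so treatment times may differ between lists and were not corrected for. Peak names of both replicate 1 MED1 lists end in B and those of the replicate 2 lists do not, which may mark 2 batches.

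Per the submitters' processing notes, Bowtie, bedtools and HOMER were used with build mm8. Versions, peak thresholds and the use of input are not given in the sources used here. The authors deposited 1 list per library, so replicates were not pooled. Each peak is a 200 bp window with a peak score set by the authors, and the lists are sorted by it. The divisor of the deposited score is not given in the sources used here. Within each list 100.0% of scores were whole multiples of a list-specific step, within 0.0055. The step ran from 0.0259 for CEBPa to 0.2384 for the second MED1 rosiglitazone list. That list began at a score of 1.43, or 6 steps, and the others began at 1.00 to 1.09, or 10 to 39 steps. The inverse of the step was 4.2 for that list, the lowest of all 15, against 10.6 to 13.3 for the other MED1 lists. If each step were 1 tag and scores were scaled by library size, that list would be the shallowest, and absence from a shallow list says less, which bears on the gained and lost calls. The labels do not say what a step is. Peak names of both NCOR lists carry 20M, while their inverse steps were 14.5 and 10.7. Read depth is unknown, and scores were used only to rank or filter peaks within a list. Positions on chromosome 1 reach 196942551, beyond the last gene end of GRCm38.p6 at 195291439. No genome or annotation of the files' build was used here, so motifs, promoters, gene lists and marker genes of other cell types were not analysed, and regions are named by mm8 coordinates counted from 1.

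Peaks were joined into sites where windows overlapped by at least 1 bp (centres at most 199 bp apart, chained). MED1 sites were called gained when both rosiglitazone lists and neither untreated list held them, lost in the opposite case, and constant when all 4 lists held them. A cofactor site was rosi-only or untreated-only when 1 of its 2 lists held it. Within a replicate pair, sites were joined from the 2 lists of that pair only. Shares carry 95% Wilson intervals, which cover counting error only. Shares of sites were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 5 transcription factors, the 4 cofactor tests or the 15 cofactor by factor tests, at an adjusted p of 0.05. Log2 odds ratios carry 95% intervals from 1000 resamplings of the 20 chromosomes, with 0.5 added to each cell where a cell was 0. Sites are not independent replicates, and with 1 list per condition such a test compares libraries, not conditions. Nothing in the labels says that the MED1 replicates came from separate cultures, so their spread may be technical. Chance overlap was taken from 12 shifts of 20 kb to 1 Mb. MED1 peak numbers were compared by an exact permutation test.

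Regions named in the text followed a rule set before the data were examined: the 10 gained, 10 lost and 5 constant MED1 sites with the highest mean within-list score percentile, and the 3 highest rosi-only and untreated-only sites per cofactor. Tests, sample groups and other settings were also chosen then. Those settings were an overlap of 50%, which for 200 bp windows is the same as centres at most 100 bp apart, the upper 50% of each list by score, lists of equal length, each MED1 list left out, the replicate number as a block, and gained and lost sites matched on score percentile. Equal length cut every list of a comparison, factor and cofactor lists included, to the shortest of them. With MED1 that was 4656 peaks, so most factor and cofactor peaks were dropped, and such values do not show list length between conditions alone. Others were chosen after seeing the data. The code was tested on simulated data for the factors at MED1 gained and lost sites, with 2150 sites: counts were recovered with an error of 0% and 5 of 5 odds ratios lay inside their interval. Each simulated site was in all lists of its class, with no dropout or replicate effect. The test thus checks the code, not whether calls hold in lists such as these. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.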

Results

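Chromatin occupancy of coactivators, a corepressor and transcription factors was mapped by ChIP-seq in 3T3-L1 adipocytes with and without rosiglitazone. MED1 is a subunit of the Mediator complex, CBP and p300 are histone acetyltransferases, and NCOR is a corepressor. CEBPa and CEBPb are C/EBP factors of adipocyte differentiation, JUND and FOSL2 are AP-1 subunits, and ATF2 is a related leucine zipper factor. The 15 lists held 4656 to 28491 peaks each and 230453 in all. They formed 67815 sites, of which 23547 were in 1 list and 336 in all 15 lists. Read depth is unknown. MED1 alone had replicates, with n = 2 lists per condition.

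The first comparison asked how MED1 occupancy differed after rosiglitazone. More MED1 peaks were listed after treatment, 7586 ± 682 (SD, n = 2) against 5158 ± 710 (SD, n = 2). The rosiglitazone list was longer in both replicates, 8069 against 5660 peaks and 7104 against 4656 peaks. The log2 ratio was 0.56, with an exact permutation p of 0.333, the smallest that 2 against 2 lists can give. The 4 lists formed 15759 MED1 sites, and 63.1% of them were in 1 list. At 743 sites MED1 was gained, at 226 it was lost and at 1236 it was constant, the last being 21.3% of the 5816 sites in at least 2 lists. With lists of equal length, 454 sites were gained and 298 lost. Leaving out untreated replicate 1 or 2 gave 1301 or 1114 gained and 1849 or 1900 lost sites, and leaving out rosiglitazone replicate 1 or 2 gave 4136 or 4028 gained and 569 or 376 lost sites.

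Replicate number divided the MED1 lists more than treatment did in total, mainly through replicate 1. Sites in both lists of 1 replicate number and neither of the other came to 1745, of which 1280 were of replicate 1 and 465 of replicate 2, against 969 for treatment (743 gained and 226 lost) and 444 for the crossed split. Untreated and rosiglitazone replicate 1 shared 33.2% of their sites (95% Wilson interval 32.3 to 34.2), while the untreated replicates shared 23.3% (22.4 to 24.3) and the rosiglitazone replicates 23.8% (23.0 to 24.5). Untreated and rosiglitazone replicate 2 shared 23.3% (22.4 to 24.1), no more than lists of the same treatment but more than the crossed pairs, at 20.1% (19.4 to 20.9) and 20.9% (20.2 to 21.7). Treatment direction still recurred between pairs. Of 1413 sites that changed in both replicate pairs, 969 (68.6%, 66.1 to 70.9) changed the same way, a log2 odds ratio of 1.80 (1.40 to 2.24, Fisher's exact p = 1.21e-24), and of 2.80 at equal length. Sites, not lists, are the units of that p, and the labels do not say that replicate numbers pair the lists. Within pair 1, 4660 sites were gained and 2248 lost, and within pair 2, 4900 and 2453.

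**Figure D1:**
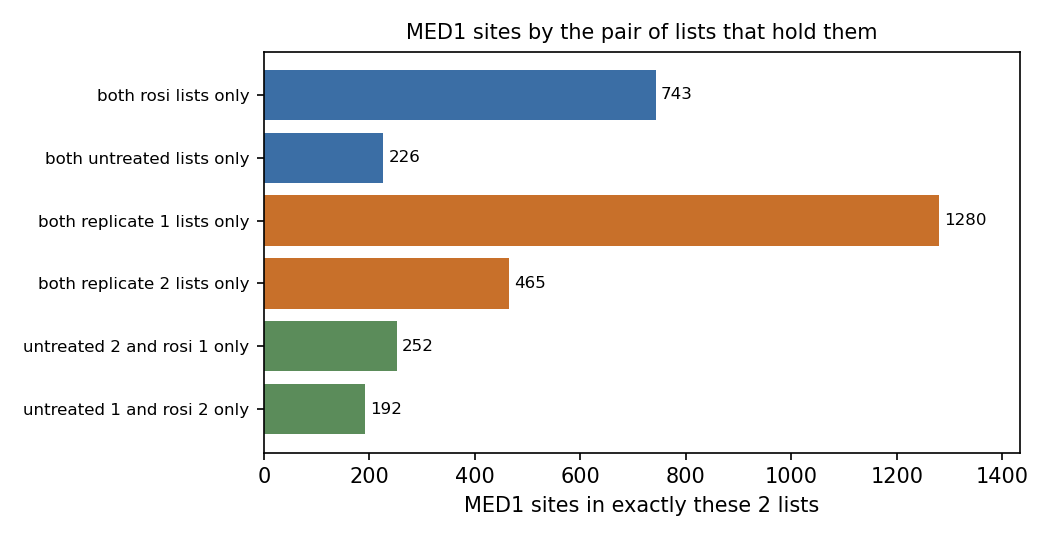
Number of MED1 sites (horizontal axis) held by exactly the 2 lists named at the left, coloured by split: treatment, replicate number and crossed. The 1280 sites of both replicate 1 lists outnumber the 743 gained and 226 lost sites.

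The gained site that ranked highest lay on chromosome 2 from 172795635 to 172795855 in mm8, with authors' scores of 5.80 and 12.39 in the rosiglitazone lists. It also held p300 and NCOR in both conditions, CEBPa, CEBPb and ATF2. The site on chromosome 5 from 28371456 to 28371673 (scores 7.08 and 7.15) and that on chromosome 14 from 65101697 to 65101908 (6.23 and 7.15) held CBP, p300 and NCOR in both conditions and none of the transcription factors. On chromosome 19 from 40490228 to 40490582, p300 was listed only after rosiglitazone and CBP only before. The other named gained sites began at 90625887 on chromosome 16, 105621024 on chromosome 4, 51883661 on chromosome 13, 94916054 on chromosome 6, 116942862 on chromosome 3 and 131080143 on chromosome 2. All 10 held p300 after rosiglitazone and NCOR in both conditions, and 6 held at least 1 transcription factor.

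The lost site that ranked highest lay on chromosome 2 from 135544627 to 135544828, with scores of 5.26 and 2.75 in the untreated lists, and was in all 11 lists of the other factors. Lost sites on chromosome 6 lay at 115205661 to 115205864, 115327862 to 115328139, 115500306 to 115500527 and 149150726 to 149150986. The rest began at 77759687 on chromosome 16, 98075142 on chromosome 5, 48341971 on chromosome 2, 34317656 on chromosome 15 and 95602683 on chromosome 10. All 10 held CBP and NCOR in untreated cells, and 9 held at least 1 transcription factor. The constant site that ranked highest, on chromosome 6 from 115477185 to 115477439, was in all 15 lists. The next constant sites began at 25100658 on chromosome 7, 50587292 on chromosome 9, 10272671 on chromosome 3 and 163684415 on chromosome 2, and all 5 held CEBPa, CEBPb and ATF2.

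The next comparison asked which factors occupied gained and lost MED1 sites before treatment. All 5 were at a lower share of gained than of lost sites. ATF2 was at 51.7% of gained sites (48.1 to 55.3) and 86.7% of lost sites (81.7 to 90.5), a log2 odds ratio of -2.61 (-3.28 to -2.11, adjusted Fisher's exact p = 1.85e-22). JUND was at 31.6% and 61.9%, a log2 odds ratio of -1.82 (-2.18 to -1.48), and FOSL2 at 20.6% and 42.5%, -1.51 (-2.01 to -1.03). CEBPa was at 30.1% and 49.1%, -1.16 (-1.69 to -0.69), and CEBPb at 35.0% and 52.7%, -1.05 (-1.55 to -0.58). Of gained sites 30.7% held none of the 5 factors, against 4.4% of lost sites, a log2 odds ratio of 3.26 (2.53 to 4.48). It was 1.31 with lists of equal length, where each factor list was also cut to 4656 peaks. The largest share expected from shifted positions was 2.65% for any factor in either class. Constant sites held CEBPa at 68.4% and CEBPb at 70.9%, above lost sites (adjusted Fisher's exact p = 2.58e-07 and 4e-07), and JUND at 71.0% passed too (adjusted p = 0.0126), while ATF2 at 91.0% (adjusted p = 0.0623) and FOSL2 at 44.9% (adjusted p = 0.513) did not. Constant sites were also stronger peaks, with a median score percentile of 79.3 against 43.2 for lost sites, and these classes were not matched on it. Of these calls, those of JUND and ATF2 depended on the settings: JUND did not pass in the upper 50% of each list or at equal length, and ATF2 passed with an overlap of 50% and at equal length.

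These contrasts depended on which MED1 lists defined the classes. Comparisons of 1 list against 1, within as well as across replicate numbers, were chosen after seeing the data. Within pair 1 the log2 odds ratios ran from -0.94 for ATF2 to -0.40 for CEBPb, and within pair 2 from -1.24 to -0.77, all 10 past the threshold. Without untreated replicate 1 all 5 turned positive, to 0.77 for ATF2, 0.68 for JUND, 0.31 for FOSL2, 0.20 for CEBPb and 0.13 for CEBPa, the last 2 not past the threshold. Without untreated replicate 2 the C/EBP factors turned to 1.09 and 1.20, while ATF2 (-0.33), JUND (-0.73) and FOSL2 (-0.70) stayed below 0 and past the threshold. Without rosiglitazone replicate 1 the values ran from -4.25 for ATF2 to -1.80 for CEBPa, and without rosiglitazone replicate 2 from -2.89 for ATF2 to -1.40 for FOSL2. With lists of equal length, the factor lists cut to 4656 peaks too, they were -1.40 for ATF2, -0.73 for JUND and -0.94 for FOSL2, still past the threshold. Leaving out an untreated list lets 1 list define a lost site while 2 still define a gained one. Leaving out a rosiglitazone list does the reverse, so that 1 list defines a gained site while 2 define a lost one. With 1 list against 1 across replicate numbers, a choice made after seeing the data, 5 of 10 values lay above 0, 2 of them past the threshold, and the other 5 lay below 0 and past it. Sites of both replicate 1 lists alone held CEBPa at 22.5% and JUND at 59.5%, against 55.3% and 34.8% for replicate 2, so factor shares also differed by replicate number. For CEBPa and CEBPb the log2 odds ratios of replicate 1 over 2, -2.09 and -2.05, were further from 0 than those of gained over lost sites, -1.16 and -1.05. ATF2 (0.93), JUND (1.46) and FOSL2 (1.11) were nearer to 0 than by treatment.

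**Figure D2:**
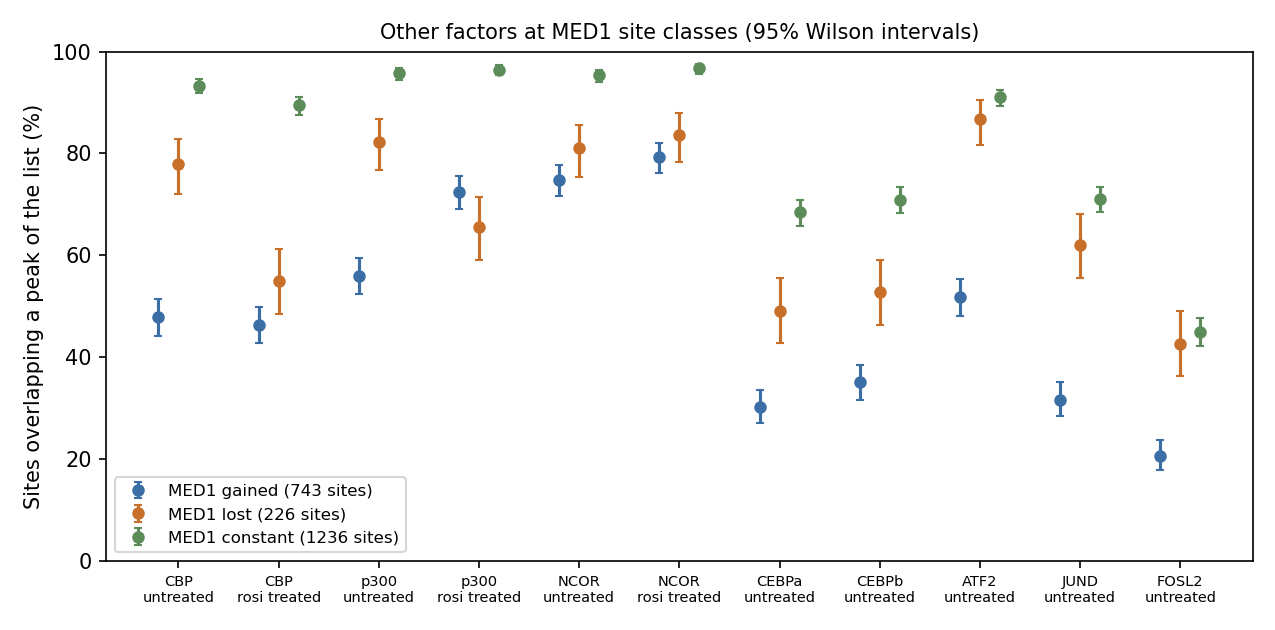
Percentage of MED1 gained, lost and constant sites (points, with 95% Wilson intervals) that overlap a peak of each list named on the horizontal axis. ATF2 is at 51.7% of gained, 86.7% of lost and 91.0% of constant sites.

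**Figure D3:**
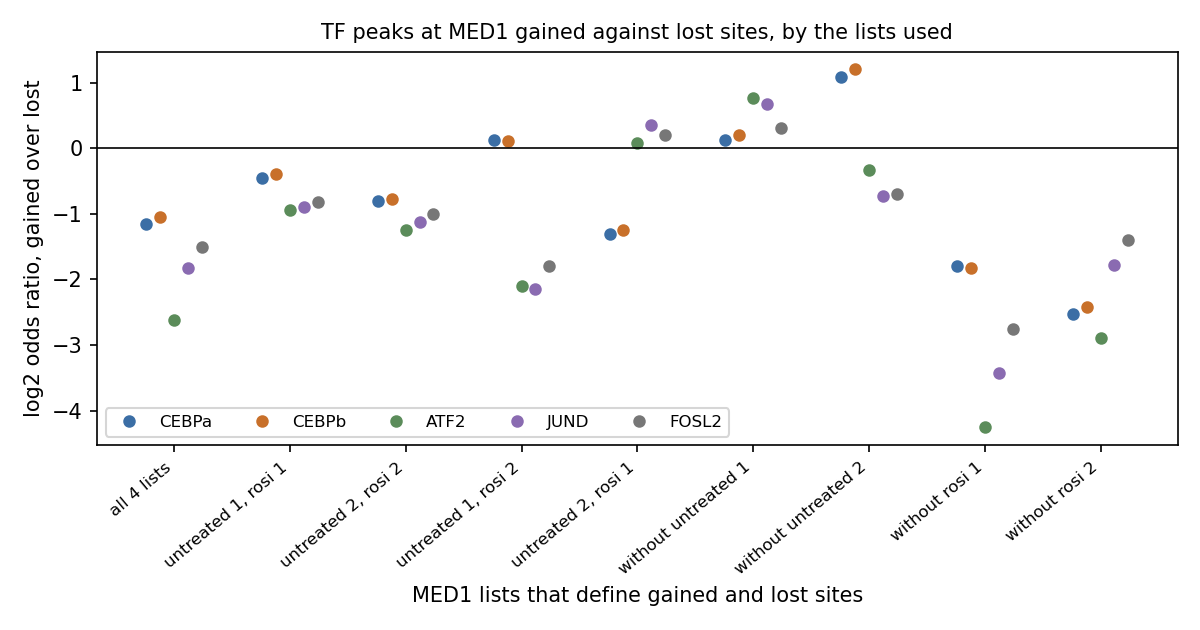
Log2 odds ratio of each transcription factor at gained over lost MED1 sites (vertical axis), by the MED1 lists that define the classes (horizontal axis). Points lie below 0 with all 4 lists and within each replicate number, and above 0 for all 5 factors without untreated replicate 1.

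Where p300 or CBP was in 1 of its 2 lists, that list was more often the rosiglitazone one at MED1 gained than at lost sites, and NCOR did not pass the test. At gained sites p300 was listed at 55.9% before and 72.4% after rosiglitazone, and at lost sites at 82.3% and 65.5%. CBP was at 47.8% and 46.3% of gained sites and at 77.9% and 54.9% of lost sites. NCOR was at 74.8% and 79.3% of gained sites and at 81.0% and 83.6% of lost sites. Of the gained sites where p300 changed, 186 of 249 were rosi-only, against 12 of 62 lost sites, a log2 odds ratio of 3.62 (2.69 to 4.81, adjusted Fisher's exact p = 2.62e-15). For CBP 89 of 189 and 4 of 60 were rosi-only, 3.64 (2.72 to 5.50, adjusted Fisher's exact p = 2.25e-09). For NCOR 75 of 117 and 24 of 42 were, 0.42 (-0.66 to 1.31, adjusted Fisher's exact p = 0.461). Within pairs the values were 1.77 and 1.01 for CBP, 1.86 and 1.73 for p300 and 0.28 and -0.02 for NCOR. This choice of lists was made after seeing the data. Without rosiglitazone replicate 1 the CBP value was 0.88 and the p300 value 2.01. Without untreated replicate 1 or 2, CBP was at 2.33 or 2.60 and p300 at 2.75 or 2.53, and without rosiglitazone replicate 2 at 2.26 and 2.56. With an overlap of 50% the CBP value was 1.91, and the p300 value was 6.87 in the upper 50% of each list and 5.81 at equal length. At equal length the cofactor lists were cut to 4656 peaks as well. Among sites where both CBP and p300 changed, CBP was rosi-only at 311 of 966 p300 rosi-only sites (32.2%) and at 188 of 1721 p300 untreated-only sites (10.9%), a log2 odds ratio of 1.95 (1.55 to 2.32, adjusted Fisher's exact p = 6.04e-40), and 3.45 in the upper 50% of each list. At most p300 rosi-only sites in this set CBP was thus untreated-only. The same held over all CBP sites, with 7491 untreated-only and 1621 rosi-only, so this majority is not particular to p300 rosi-only sites. Each cofactor had 1 list per condition, so these tests compare libraries. CBP and p300 shares also differed by replicate number. At sites of both replicate 1 lists alone p300 was at 87.8% before and 84.1% after rosiglitazone, against 52.3% and 39.8% for replicate 2. CBP was at 79.1% and 65.3%, against 52.3% and 39.6%. NCOR differed less, at 74.2% and 75.9% against 66.5% and 73.1%. How far this enters the relation to MED1 change was not tested.

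The cofactor lists differed in how many sites each condition held. CBP had 15383 peaks before and 9515 after rosiglitazone, with 7491 untreated-only sites (44.1%, 43.3 to 44.8), 1621 rosi-only sites (9.5%, 9.1 to 10.0) and 7891 in both. p300 had 15007 and 13746 peaks, with 5633 untreated-only, 4362 rosi-only and 9373 shared sites. NCOR had 25136 and 28491 peaks, with 6227 untreated-only, 9577 rosi-only and 18899 shared sites. With lists of equal length CBP had 2930 untreated-only and 2928 rosi-only sites, nearly equal by construction.

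All 5 factors were at a lower share of p300 rosi-only than untreated-only sites, with log2 odds ratios from -0.92 for FOSL2 (-1.05 to -0.78, 19.3% against 31.1%) to -0.63 for CEBPb (-0.79 to -0.48, 19.7% against 27.6%). In the upper 50% of each list CEBPa moved from -0.68 to -1.02 and CEBPb to -0.96. At CBP sites ATF2 (-0.60), FOSL2 (-0.32) and JUND (-0.21) were lower at rosi-only sites, while CEBPa (0.04, adjusted Fisher's exact p = 0.723) and CEBPb (0.01, 0.902) did not pass. With lists of equal length those C/EBP values turned to -0.82 and -0.88, while ATF2, FOSL2 and JUND were at -1.37, -0.50 and -0.68, and at -0.90, -0.56 and -0.54 in the upper 50% of each list. At equal length the factor lists were cut to 9515 peaks along with the untreated CBP list. With an overlap of 50% JUND no longer passed (-0.16, adjusted Fisher's exact p = 0.059). At NCOR sites ATF2 (-0.31), JUND (-0.33) and FOSL2 (-0.21) were lower. None of these 3 passed in the upper 50% of each list or at equal length. CEBPa and CEBPb then passed, at 0.41 and 0.37 in the upper 50% and at 0.45 each at equal length. There the equal length was 12332 peaks, for NCOR and factor lists alike. ATF2 was at 85.5% of CBP, 75.7% of p300 and 57.2% of NCOR sites held in both conditions. The factors were mapped in untreated cells only. A lower share at rosi-only sites thus cannot be told apart from the condition of the factor lists. These classes were not matched on score.

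The rosi-only sites that ranked highest for CBP (chromosome 17, 39451379 to 39451578, score 17.32, and chromosome 11, 97968535 to 97968734, score 10.56) lay beside 2 of the 3 for p300, at 39451398 on chromosome 17 and 97968472 on chromosome 11. The untreated-only sites that ranked highest for CBP and p300 began at 39455786 and 39455784 on chromosome 17. None of these held MED1 or a transcription factor, and the 3 NCOR rosi-only sites, at 77706791, 77723654 and 77726899 on chromosome 2, held none either. On chromosome 17 the rosi-only and untreated-only sites lay close together, though of opposite classes, and so did the 3 NCOR sites on chromosome 2. The use of input is not known, so background signal at these sites was not excluded. The third CBP rosi-only site began at 92164570 on chromosome 16 and the other p300 site at 117140137 on chromosome 10. Further untreated-only sites began at 40490307 on chromosome 19 and 38722599 on chromosome 6 for CBP, and at 129195972 and 114799581 on chromosome 6 for p300. Those of NCOR began at 107183433 and 121876457 on chromosome 9 and 5845305 on chromosome 19.

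The last comparison asked which factors shared sites in untreated adipocytes. CEBPa and CEBPb shared most, 92.0% of CEBPa peaks (91.5 to 92.5) against 0.51% for shifted positions. FOSL2 shared 68.6% of its peaks with JUND (68.0 to 69.2). ATF2 overlapped 51.1% of CEBPa, 48.2% of CEBPb, 48.5% of JUND and 35.1% of FOSL2 peaks. The C/EBP and AP-1 lists shared 21.3% to 30.3%. The largest chance share for any pair was 1.26%. Of 49656 sites with any of these factors, 19912 held 1 and 1879 held all 5.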

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

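The tests in this part were chosen after the results were seen, except that of sites held by p300, whose prediction was written first, and the counts of MED1 sites by treatment and by replicate number and the factors at gained and lost sites were planned.

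The number of CBP peaks was lower after rosiglitazone, with a log2 ratio of -0.69, and that of p300 peaks with -0.13, while both MED1 replicates had more peaks. The difference between factors was not tested, since CBP and p300 had 1 list per condition. At MED1 gained sites p300 changed towards rosi-only more than CBP did, by a log2 odds ratio of 1.73 (chromosome resampling interval 1.20 to 2.26). Over all p300 and CBP sites the same contrast was 1.84 (1.73 to 1.95), so the difference was not particular to gained sites. List length enters both values. At equal length rosi-only and untreated-only sites were nearly equal by construction, at 2928 and 2930 for CBP and 4768 and 4777 for p300. The contrast at gained sites was not run at equal length. The relation to MED1 change was higher for CBP than for NCOR by 3.22 (2.10 to 5.32) and for p300 than for NCOR by 3.20 (1.73 to 4.86) on the log2 scale. Without rosiglitazone replicate 1 these differences fell to 0.62 (-0.13 to 1.61), an interval that includes 0, and 1.75 (0.85 to 2.86), and with any other MED1 list left out they lay between 2.01 and 2.77. Peak names of the NCOR rosiglitazone list carry 30m and those of the second MED1 rosiglitazone list 1h. Unequal treatment time may thus enter these differences.

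MED1 lists shared more sites by replicate number than by treatment, with a ratio of 1.80 (1.67 to 1.94), mainly through replicate 1. The 1280 sites of both replicate 1 lists alone outnumbered the 743 gained sites, while the 465 of replicate 2 did not, though they outnumbered the 226 lost sites. At equal length there were 804 and 466, against 454 gained and 298 lost sites. Unequal list length does not account for it, since the ratio was 1.69 (1.52 to 1.89) at equal length. The lower 50% of peaks does not alone either, since it was 1.72 (1.49 to 2.03) among sites in the upper 50% by score of the lists that held them and absent from the full other lists. With every list cut to its upper 50% it was 1.48 (1.32 to 1.69). The upper 50% began at scores of 1.52 to 2.15 in the MED1 lists, against lowest scores of 1.02 to 1.43. Peaks not far above the calling threshold thus remained, and their part stays open. Without the second rosiglitazone list and at equal length, sites in untreated 1 and rosi 1 alone outnumbered those in both untreated lists alone by a ratio of 2.48 (2.15 to 2.88), so that list alone does not account for it. Nor does an unequal treatment time, since both untreated lists had none and would share the most with each other. For replicate 2, without the first rosiglitazone list, the ratio was 1.35 (1.11 to 1.64). A batch or a difference between cultures stays open, since the labels name neither for ChIP-seq. Read depth stays open too, since it is unknown and equal list length does not make it equal. The inverse of the score step was 13.3 and 11.7 for the replicate 1 lists, against 10.6 and 4.2 for replicate 2.

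The transcription factors were at a lower share of MED1 gained than lost sites. Replicate number is not the whole cause, since within each number the value nearest to 0 was -0.40 (-0.55 to -0.26), although values across numbers lay on both sides of 0. Within each number the rosiglitazone list was longer, and these values were not run at equal length or matched on score. List length thus stays open there. Among sites held by p300 in the matching condition the value nearest to 0 was -1.00 (-1.54 to -0.48), so the fall to 0 predicted for background peaks was not seen. That does not exclude background peaks. Lost sites were kept by p300 from untreated cells, like the factor lists, and gained sites by p300 from treated cells. The filter itself may thus favour factors at lost sites. That the factors were mapped in untreated cells only cannot be told apart from treatment, because no list from treated cells was used. The same choice turned the sign for p300 alone: gained over lost was -1.88 (-2.23 to -1.52) with its untreated list and 0.47 (0.04 to 0.88) with its rosiglitazone list. CBP stayed below 0, at -1.94 (-2.24 to -1.64) and -0.50 (-0.84 to -0.15), and NCOR was at -0.52 (-1.08 to -0.07) and -0.42 (-0.99 to 0.07). No biological explanation was tested.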

How the results depend on the processing

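Leaving out 1 MED1 list moved gained sites to between 1114 and 4136 and lost sites to between 376 and 1900, because 1 list then defined a class or 1 opposite list had to lack the site. CEBPa at gained against lost sites then ran from -2.53 to 1.09, CEBPb from -2.42 to 1.20, ATF2 from -4.25 to 0.77, JUND from -3.43 to 0.68 and FOSL2 from -2.76 to 0.31. Without untreated replicate 1 they were 0.13, 0.20, 0.77, 0.68 and 0.31, and without untreated replicate 2 the C/EBP values were 1.09 and 1.20. NCOR against MED1 change ran from -0.21 to 0.51. With all 4 lists kept, 25 of 25 alternative values of these factors stayed below 0 and past the threshold, from -2.79 to -0.73. Over 12 alternatives CBP against MED1 change stayed past the threshold (0.88 to 3.53), as did p300 (1.25 to 6.87). NCOR passed in 2 of 12, with opposite signs: 0.55 for untreated 1 with rosi 2 and -0.42 for untreated 2 with rosi 1.

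Labels share replicate numbers without saying that they pair the samples, although peak names of both replicate 1 MED1 lists end in B. With the replicate block, the mean paired log2 ratio of MED1 peak number was 0.56, where the smallest sign-flip p is 0.5, and gained and lost sites within pairs averaged 4780 and 2350, because 1 list then defined a class. Alternatives chosen after seeing the data crossed the numbers: untreated 1 with rosi 2 gave 0.12 for CEBPa, 0.11 for CEBPb and 0.55 for NCOR, and untreated 2 with rosi 1 gave 0.08 for ATF2, 0.36 for JUND, 0.20 for FOSL2 and -0.42 for NCOR. Of the 5 factor values above 0, 2 passed, and the other 5 stayed below 0, from -2.14 to -1.24. NCOR was -0.02 within pair 2, likewise chosen after seeing the data. Sites in the upper 50% by score and absent from the full opposite lists came to 326 gained and 58 lost.

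In the upper 50% of each list there were 101 lost and 816 constant MED1 sites, 574 and 3509 CBP, 1965 and 2599 p300 and 4255 and 2576 NCOR rosi-only and untreated-only sites, fewer by construction. The replicate number split held 884 sites and the crossed split 162. FOSL2 at lost against constant sites turned to 0.42 and JUND there no longer passed (-0.01), and 0 factors passed as lower at NCOR rosi-only sites. With lists of equal length there were 454 gained sites, 279 crossed sites, and 2928 CBP rosi-only and 2930 untreated-only sites. NCOR against MED1 change turned to -0.30 and FOSL2 at lost against constant sites to 0.26, where JUND no longer passed (-0.32) and ATF2 passed (-0.93, and -0.94 with 50% overlap). At CBP sites all 5 factors passed as lower, CEBPa at -0.82 and CEBPb at -0.88, and at NCOR sites 0 did, with the factor lists cut as well. The median factor overlap moved from 41.6% to 38.8% with 50% overlap, 35.9% in the upper 50% and 32.8% at equal length. Except where stated, the cause was not tested. Of 367 alternative values, 273 stayed the same in direction, side of the threshold or size, but 86 of these are named sites, whose high scores keep them under either score setting by construction. Overlap, score and length settings give no value for MED1 peak number, and motif, promoter and gene list alternatives were not run. Unknown depth limits all absences.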

Other observations

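All tests in this part were chosen after the results were seen.

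The cofactors were spread unevenly over the transcription factor peaks of untreated cells. NCOR was at 62.6% of CEBPa peaks (95% Wilson interval 61.7 to 63.4), 57.8% of CEBPb, 52.4% of ATF2, 36.5% of JUND and 27.1% of FOSL2 peaks (26.5 to 27.7). CBP was at 46.0% of ATF2, 43.3% of CEBPa and 27.3% of FOSL2 peaks. The first untreated MED1 list held 17.8% of ATF2 and 17.0% of CEBPa peaks, and the second 13.3% and 18.1%. JUND or FOSL2 without a C/EBP factor was at 31.0% of MED1 lost sites (25.3 to 37.3), 18.6% of constant sites (16.5 to 20.9) and 20.3% of gained sites (17.6 to 23.4). By replicate number it was at 43.5% of sites of both replicate 1 lists alone (40.8 to 46.2) and 11.8% of those of replicate 2 (9.2 to 15.1). These differences were not tested. All 5 factors together were at 6.2% of gained, 19.9% of lost and 27.4% of constant sites.

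Several named lost sites lay close together on chromosome 6, near the constant site that ranked highest. A hypothesis that lost sites cluster was tested by redrawing 226 lost sites among MED1 sites in at least 2 lists. The fullest 500 kb window held 3 lost sites, a count reached in nearly all of 10000 draws (permutation p = 0.969), so the test gave no sign of clustering among all lost sites. It did not test whether the named lost sites, ranked by score, lay closer together than others.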
